A study of Mus musculus with 105 samples.

How the data were processed

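Liver RNA of DEN-treated mice was sequenced on an Illumina HiSeq2000 after library preparation by MAPS, a method that counts polyadenylated 3′ ends. Per the submitters' processing notes, reads were aligned with STAR 2.7.10a to GRCm38/mm10, counted with HTSeq 2.0.2 and processed with DESeq2 1.32.0. The deposited values are on a log2 scale after a variance-stabilising transform, 1 value per gene and library for 12966 genes and 105 libraries. The name of the deposited table mentions other scales, so the scale was checked on the values. All libraries shared a floor of 3.8289, which stood for 0 reads, and undoing the transform gave whole reads for 100.0% of values within 0.05. Recovered reads served for depths, levels and 1 alternative, and the tests used the deposited values. Because the transform compresses low values, differences of genes with few reads are understated.

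Reads over the listed genes ranged from 4676444 to 20231121 per library (median 8353515). Reads carried no molecular identifiers as deposited, so counting error is a lower bound of the error and all errors given are spreads between libraries. Over all 5460 pairs of libraries the lowest chi-square per gene was 4.924, so no library was a copy of another. Genotype, stage, tissue, replicate number and sequencing group were taken from the labels, and 0 columns were left out. A minimum mean of 3 on the deposited scale removed no gene, and 4 symbols appeared more than once and were kept apart. Gene positions were matched for 12898 genes.

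The comparisons, gene lists, rule for naming genes and first alternatives were fixed before the data were examined. Each sequencing group was fitted on its own in R 4.3.3 with limma 3.58.1, with 1 mean per group, empirical Bayes moderation with a trend on the mean, and Benjamini-Hochberg adjustment per comparison. A gene was called at an adjusted p below 0.05. The comparisons were each knockout against WT over the 4 non-tumour stages with equal weight, its interaction with stage, knockout against WT in tumours, tumour against non-tumour liver at 8 months in each genotype, the difference of that effect between knockout and WT, and age in WT. Sequencing groups were not compared directly. The 29 gene lists were tested with limma's camera and a correlation between genes estimated from the data, adjusted over 580 pairs of list and comparison. "Likewise" after a p stands for the same test. Lists without a called gene are given with the number of genes measured.

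Genes were named by a fixed rule. It took the 4 targeted genes, then the 6 largest rises and 6 largest falls among called genes that lay on the same side of WT at all 4 stages, or whose groups did not overlap in comparisons of a pair of groups. It took 4 and 4 for age and for differences of the tumour effect, and the 6 smallest p for interactions. From each list it took up to 3 called members with the smallest p, or up to 2 with the highest mean where none was called. Predicted genes and genes without a symbol were passed over, and some genes the rule takes are not reported here. The text gives the named genes that show each result best.

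Concordance of knockouts was the Pearson correlation of effects across genes, with the expected overlap of calls from their shares. For pairs that shared WT libraries the covariance was compared with 20 simulations without effects, and IKO and SKO were also compared over 20 splits with separate WT libraries. Near each targeted locus, called genes within 10 Mb were counted and compared with 12463 to 12747 windows of the same width elsewhere. For each comparison the libraries were also split in other ways, and the genes called were counted.

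Alternatives were no filter, a stricter filter that left 10471 and 10544 genes, quantile normalization, only the groups of the comparison, a replicate block, moderation without a trend, library weights, leaving out 1 library and the preset correlation of 0.01. Those added after the data were seen were limma-voom on the recovered reads, leaving out a doubted library, lists with 1 library left out, concordance from different stages and a replicate block for MKO at 8 months. Whether replicate numbers pair libraries was checked in 28 pairs of groups. In BKO tumour and non-tumour liver every same-number pair correlated at 0.23 to 0.33, and in MKO and WT 8-month non-tumour liver at 0.12 to 0.30. The remaining 26 had no such pattern, and the blocked fit was run throughout as an alternative.

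The fit was tested on simulated data with changes added to the spread of each gene, averaged over all groups of a sequencing group. In non-tumour liver 2-fold changes were recovered in 80.9% (IKO), 77.5% (SKO), 78.3% (BKO) and 81.2% (MKO) of genes, and in tumours in 55.2%, 42.6%, 54.0% and 56.3%. Changes of 1.5-fold were recovered in 63.5%, 61.2%, 56.8% and 74.2% in non-tumour liver and in 9.59%, 22.1%, 14.1% and 20.6% in tumours. Changes of 4-fold were recovered in 78.7% to 81.4% in tumours, so a gene not called there may have changed by 2-fold or more. For interactions 2-fold changes were recovered in 27.4% to 35.1% of genes and 1.5-fold changes in 1.41% to 5.97%. Unchanged genes made up 1.47% to 12.0% of calls. In the data the median spread was 1.07 (sequencing group 1) and 1.23 (sequencing group 2) times as large in tumours as in non-tumour liver. The simulated values for tumours may thus be too favourable. A list moved in simulation was called in all 4 tests. Simulated genes were drawn independently of each other. The simulation therefore does not show how often a moved list is called where its genes vary together. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.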

Results

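RNA was measured in the livers of mice treated with diethylnitrosamine (DEN), a chemical carcinogen that produces liver tumours. The labels give 30 groups. Sequencing group 1 held 60 libraries of IKO (labelled Ikk KO), SKO (Shp2 KO, gene Ptpn11) and wild-type (WT) mice, with n = 4 per group. Sequencing group 2 held 45 libraries of BKO (β-catenin KO, gene Ctnnb1), MKO (cMet KO, gene Met) and a second set of WT libraries, with n = 3 per group. The study's title places each loss in hepatocytes. Each genotype was sampled at 1, 3 and 5 months and at 8 months, when tumours and the non-tumour liver were taken separately. Reads over the listed genes ranged from 4676444 to 10863046 per library in sequencing group 1 and from 6650086 to 20231121 in sequencing group 2. Differences below are log2 differences ± SE from limma with its adjusted p, and levels are normalised read counts ± SD. The p-values measure the spread between libraries, because the labels number biological replicates but do not say that each came from a separate animal.

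Whether the targeted transcripts fell was asked first. Ptpn11 (GRCm38 chromosome 5, 121130533 to 121191397), which encodes the phosphatase SHP2, fell in SKO non-tumour liver (−1.12 ± 0.08, adjusted p = 6.18e-16) and in SKO tumours (−1.14 ± 0.16, adjusted p = 3.17e-06). Its level at 1 month was 148.4 ± 27.23 in SKO and 373.6 ± 32.68 in WT (n = 4 each). At 3 months the SKO mean was 188.3 ± 126.7, since the library labelled replicate 2 held 375.1 normalised reads, among the WT values of 350.1 to 387.7. Ikbkb (chromosome 8, 22659205 to 22706589), which encodes the kinase IKKβ, fell in IKO non-tumour liver (−0.32 ± 0.07, adjusted p = 0.00258) and differed by −0.35 in IKO tumours (adjusted p = 0.19). The fall was not seen at 3 months, with 352.9 ± 18.59 in IKO and 340.4 ± 93.46 in WT, against 205.5 ± 28.22 and 344.1 ± 57.68 at 1 month (n = 4 each). The labels do not say which IKK subunit was deleted. Met (chromosome 6, 17463349 to 17573980), the receptor of hepatocyte growth factor, fell in MKO non-tumour liver (−0.31 ± 0.07, adjusted p = 0.0118) and in MKO tumours (−0.50 ± 0.14, adjusted p = 0.042, or 0.387 when the tumour groups were fitted alone). At 3 months it averaged 223.1 ± 42.11 in MKO and 224.3 ± 12.99 in WT, and in non-tumour liver at 8 months 155.0 ± 8.054 and 242.5 ± 47.46 (n = 3 each). Ctnnb1 (chromosome 9, 120933400 to 120960507), which encodes β-catenin, differed by −0.01 ± 0.07 in BKO non-tumour liver (adjusted p = 0.931) and by −0.05 ± 0.14 in BKO tumours (adjusted p = 0.946). The method counts reads near the 3′ ends of transcripts, where a transcript that lost an internal exon is still counted. Among the genes targeted in other lines, Met was lower by 0.23 in SKO non-tumour liver (adjusted p = 0.0221) and Ctnnb1 higher by 0.21 in IKO (adjusted p = 0.0472).

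**Figure D1:**
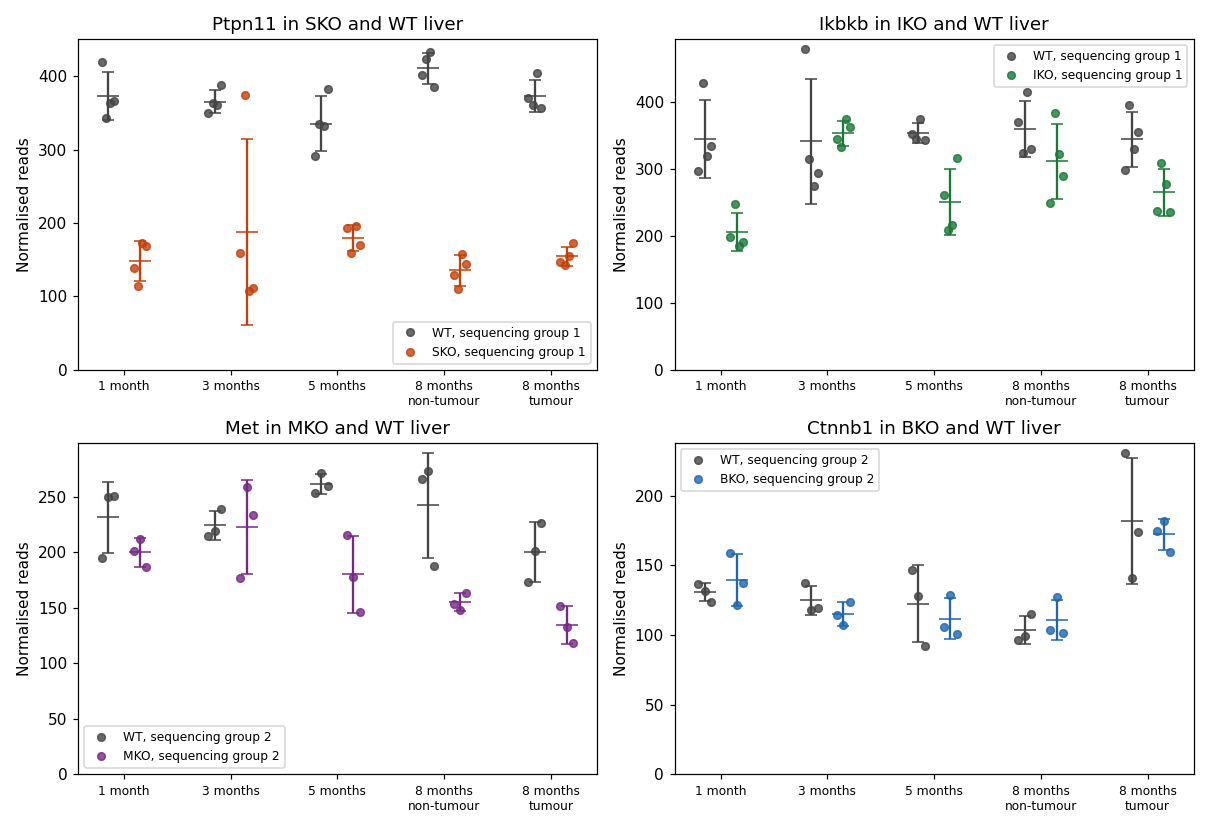
Normalised read counts of the 4 targeted genes in each library by stage and genotype. Ptpn11 in SKO averaged 148.4 at 1 month against 373.6 in WT, while Ctnnb1 in BKO averaged 139.5 against 130.8.

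IKO and WT non-tumour livers were compared over the 4 stages to ask what loss of IKK did before and beside tumours (16 libraries each). Tmc5, a transmembrane channel-like gene, rose by 2.23 ± 0.20 (adjusted p = 7.16e-12) and Gdpd3, a lysophospholipase D, by 1.60 ± 0.21 (adjusted p = 4.26e-07). Apoa4, an apolipoprotein of lipid transport, rose by 1.41 ± 0.27 (adjusted p = 0.000347). The fucosyltransferase Fut10 rose by 1.24 ± 0.12 and the mitochondrial transhydrogenase Nnt by 1.03 ± 0.11. Papss1, which makes the donor for sulfation, fell (−1.35 ± 0.10, adjusted p = 5.5e-16) and Cyb561, a transmembrane electron carrier (−1.70 ± 0.13, adjusted p = 2.94e-15). Camk1d fell (−1.31 ± 0.13), the ubiquitin ligase Rnf170 (−1.20 ± 0.10), Trim30d (−1.17 ± 0.13) and the defensin Defb1 (−1.07 ± 0.12). In all, 1172 genes passed, 502 higher and 670 lower, of which 6 and 11 moved at least 2-fold. At single stages 1189 genes passed at 1 month and 26, 188 and 26 at 3, 5 and 8 months.

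Among the fixed lists in IKO, 5 of 16 glycolysis genes were higher and 0 lower, including Ldha by 0.42, Gpi1 by 0.35 and Tpi1 by 0.22 (adjusted p = 0.435 with an estimated correlation). Fatty acid oxidation had 4 of 22 higher, including the carnitine transferase Cpt1a by 0.35 and Acadvl by 0.28 (adjusted p = 0.689 with an estimated correlation). Xenobiotic genes had 3 of 22 lower, Cyp2b10 by −0.87, Ugt1a1 by −0.57 and Cyp2d22 by −0.37 (adjusted p = 0.84 with an estimated correlation). Of immune lists, antigen presentation had 2 of 18 higher (Nlrc5 by 0.35, Psmb10 by 0.24; adjusted p = 0.513 with an estimated correlation). Macrophage markers had 2 of 21 (Cd5l by 0.65, C1qb by 0.39; adjusted p = 0.733 likewise) and T and NK cell markers 2 of 12 (Gzma by 0.49, Nkg7 by 0.35; adjusted p = 0.692 likewise). Lipogenesis had 2 of 25 lower (Cd36 by −0.61, Elovl6 by −0.54) and cholesterol synthesis 2 of 22 higher and 1 lower, Hmgcs1 by −0.82. NF-κB target genes had 1 of 21 higher, the chemokine Ccl5 by 0.47, and 0 lower (adjusted p = 0.804 with an estimated correlation). Single calls were Slc27a5 by 0.75 and Abcc2 by −0.30 (bile acids), Ahr by −0.55 (pericentral, median 0.01, mean −0.02) and Hsd17b6 by 0.88 (periportal, median −0.04, mean 0.01). Further calls were Rsad2 by −0.45 (interferon), Gsta3 by 0.39 (NRF2), Manf by 0.47 (endoplasmic reticulum stress), Bank1 by −0.34 (B cells) and ND5 by −0.31 (mitochondrial genome). Adjusted over the list alone, 6 fatty acid oxidation genes, 5 endoplasmic reticulum stress genes and 5 antigen presentation genes were higher. The other 12 lists held 0 called genes. These were proliferation (29 measured), oncofetal (18), cholangiocyte (14), stellate (24), neutrophil (10), sinusoidal endothelium (18), erythroid (8), acute phase (25), p53 (22), male-biased (20), female-biased (13) and ERK targets (18). Without the WT 3-month library labelled replicate 1 the count was 781.

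SKO and WT non-tumour livers were compared in the same way (16 libraries each) and 1554 genes were higher and 1411 lower. Csad, an enzyme of taurine synthesis, rose by 2.65 ± 0.24 (adjusted p = 1.27e-12) and Asns, asparagine synthetase, by 2.63 ± 0.30 (adjusted p = 1.55e-09). The fatty acid hydroxylase Cyp4a14 rose by 2.31 ± 0.42, Cyp2c69 by 2.32 ± 0.37 and the lipid droplet gene Cidec by 1.99 ± 0.30. Pebp1, known as Raf kinase inhibitor protein, rose by 2.21 ± 0.09 (adjusted p = 4.44e-26), from 649.4 to 903.0 mean normalised reads across WT stages to 2406 to 5087 in SKO. Major urinary protein genes, secreted by male liver, fell: Mup17 (−3.23 ± 0.45, adjusted p = 1.89e-07), Mup11 (−3.13 ± 0.51), Mup7 (−2.65 ± 0.34), Mup3 (−2.56 ± 0.25) and Mup1 (−2.31 ± 0.27). Hsd3b5, a male-biased steroid dehydrogenase, fell (−2.93 ± 0.41, adjusted p = 1.85e-07).

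The list of male-biased liver genes had 12 of 20 lower and 2 higher in SKO (median −0.89; adjusted p = 0.539 with an estimated correlation). Periportal genes had 11 of 20 lower, including the histidine-degrading enzymes Hal by −0.90 and Uroc1 by −0.85 and the urea cycle gene Asl by −0.52 (adjusted p = 0.385 with an estimated correlation). Cholesterol synthesis had 15 of 22 higher, including Cyp51 by 0.81 and Acat2 by 0.65 (adjusted p = 0.477 with an estimated correlation). Macrophage markers had 15 of 21 higher, including Cd5l by 1.09, Lyz2 by 0.92 and C1qb by 0.84 (adjusted p = 0.36 with an estimated correlation). Proliferation genes had 12 of 29 higher, including Ube2c by 0.61, Ccna2 by 0.54 and Cdk1 by 0.51 (adjusted p = 0.539 with an estimated correlation). NRF2 targets had 11 of 25 higher, including Gpx2 by 1.14, Ugdh by 1.06 and Ephx1 by 0.90 (adjusted p = 0.388 with an estimated correlation). Lipogenesis had 10 of 25 lower and 4 higher, with Pklr by −1.14 and Acaca by −0.79 (adjusted p = 0.733 with an estimated correlation). Of the ERK targets, which report signalling below SHP2, 4 of 18 were lower and 1 higher: Spred1 fell (−0.72 ± 0.08, adjusted p = 2.82e-09), as did Spry4 (−0.57) and Spred2 (−0.37). The list median was 0.01, its mean −0.09 and its test downward (adjusted p = 0.733 with an estimated correlation).

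Stellate cell and fibrosis genes had 7 of 24 higher in SKO, with Col1a1 by 0.93 and Lum by 0.69 (adjusted p = 0.65 with an estimated correlation). Oncofetal genes had 6 of 18 higher, with Ly6d by 1.70 and Scd2 by 1.28 (adjusted p = 0.633 likewise). Cholangiocyte genes had 5 of 14 higher, with Krt8 by 0.54 and Krt18 by 0.37 (adjusted p = 0.722 with an estimated correlation). Bile acid genes had 7 of 20 higher and 3 lower, with Cyp7a1, the rate-limiting enzyme of bile acid synthesis, by 1.47 and the exporter subunit Slc51b by 1.02 (adjusted p = 0.858 likewise). Fatty acid oxidation had 6 of 22 higher and 2 lower, with Acaa1b by 1.09 and the regulator Ppara by −0.55 (adjusted p = 0.804 likewise). Xenobiotic genes had 5 higher and 6 lower of 22, with Cyp2a5 by 1.52 and the receptor Nr1i3 by −0.66 (median −0.05, mean 0.02, test downward, adjusted p = 0.966 likewise). Interferon genes had 5 of 23 lower and 2 higher (Mx1 by −0.38), and antigen presentation 5 of 18 lower and 1 higher (Psmb9 by −0.41). NF-κB genes had 5 of 21 higher (Tnfaip3 by 0.37, Icam1 by 0.35; adjusted p = 0.802 with an estimated correlation). Acute phase genes had 5 of 25 (Saa2 by 1.59, Saa3 by 0.70; adjusted p = 0.967 likewise). B cell markers had 5 of 15 higher (Igkc by 1.31) and glycolysis 3 of 16 higher (Hk2 by 0.55). Mitochondrial genes had 3 of 7 lower and endoplasmic reticulum stress genes 2 of 19 higher and 1 lower, Xbp1 by −1.16. Adjusted over the list alone, 10 B cell markers were higher and 6 mitochondrial genes lower. Further calls fell among p53 targets (3 higher, 1 lower of 22), erythroid cells (3 and 1 of 8), T and NK cells (1 and 1 of 12), and neutrophils (1 and 0 of 10). Female-biased genes had 3 higher and 2 lower of 13, pericentral genes 3 and 1 of 22, and sinusoidal endothelium 0 of 18. Without the library labelled SKO 3m replicate 2 the count of 2965 became 3167.

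BKO and WT non-tumour livers were compared to ask what loss of β-catenin did (12 libraries each). Genes of the pericentral zone, which WNT and β-catenin signalling maintains, fell: Cyp2e1, the ethanol- and DEN-metabolising cytochrome (−4.27 ± 0.37, adjusted p = 1.34e-10), the glutamate transporter Slc1a2 (−4.06 ± 0.34, adjusted p = 4.49e-11) and Lect2 (−3.61 ± 0.26, adjusted p = 3.17e-12). Cyp2c37 (−3.54 ± 0.26), Rgn (−3.07 ± 0.27) and the aminotransferase Oat (−2.88 ± 0.28) fell as well. Cyp2e1 averaged 79.7 normalised reads in BKO and 5270 in WT at 1 month, and 2082 and 7417 at 8 months (n = 3 each). Cyp2b10, a target of the nuclear receptor CAR, rose by 3.08 ± 0.29 (adjusted p = 7.74e-10). Tff3, a trefoil peptide, rose by 3.04 ± 0.41. Cib3 rose by 1.90 ± 0.25 and the metallothioneins Mt1 and Mt2 by 1.67 ± 0.40 and 1.60 ± 0.47. In all, 2540 genes passed, 1368 higher and 1172 lower.

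Of 22 measured pericentral genes 20 were lower in BKO and 0 higher (median −1.63), including the transcription factor Tbx3 by −2.84. This list gave the smallest p of all lists, adjusted p = 0.0582 with an estimated correlation. Stellate and fibrosis genes had 20 of 24 higher, including Mmp2 by 1.11, Loxl1 by 0.94 and Bgn by 0.86 (adjusted p = 0.205 with an estimated correlation). Macrophage markers had 10 of 21 higher, including Trem2 by 1.03, Mpeg1 by 0.71 and Cx3cr1 by 0.67 (adjusted p = 0.48 with an estimated correlation). Cholangiocyte and progenitor genes had 8 of 14 higher, including Sox9 by 1.317, Krt7 by 0.75 and Sox4 by 0.69 (adjusted p = 0.354 with an estimated correlation). Periportal genes had 7 of 20 higher, including Aldh1b1 by 1.26 and Cdh1 by 1.03 (adjusted p = 0.477 with an estimated correlation). Among p53 targets 4 of 22 were higher, including the cell cycle inhibitor Cdkn1a by 1.53 ± 0.17 (adjusted p = 1.87e-08) and Btg2 by 1.03, and 1 was lower (adjusted p = 0.769 with an estimated correlation). Xenobiotic genes had 10 of 22 lower and 3 higher (Cyp2c38 by −2.29; adjusted p = 0.546 likewise). Fatty acid oxidation had 6 of 22 lower (Cyp4a10 by −1.64, Vnn1 by −1.27; adjusted p = 0.681 likewise). Bile acid genes had 6 of 20 lower and 2 higher, with the uptake carrier Slco1b2 by −1.98 (adjusted p = 0.478 likewise).

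Acute phase genes had 9 of 25 higher in BKO and 1 lower (Hpx by 0.97, Crp by −0.46; adjusted p = 0.555 with an estimated correlation). Male-biased genes had 5 of 20 lower and 2 higher (Hsd3b5 by −2.40, Elovl3 by −2.30), and NRF2 genes 5 of 25 higher and 2 lower (Gsta3 by −0.85, Gsta1 by 0.77). ERK targets had 3 of 18 higher (Egr1 by 1.19, Jun by 0.81, Fos by 0.71; adjusted p = 0.689 with an estimated correlation). Glycolysis had 4 of 16 higher and 1 lower (Pfkp by 0.66, Pfkfb3 by −0.84). Proliferation had 4 of 29 higher (Mcm5 by 0.61, Ccna2 by 0.44) and oncofetal genes 3 of 18 higher and 1 lower (Scd2 by 1.33, Meg3 by −1.57). Lipogenesis had 3 of 25 lower (Mlxipl by −0.55), interferon genes 3 of 23 higher and endoplasmic reticulum stress genes 2 of 19 lower (median −0.04, mean 0.01). Cholesterol synthesis had 4 of 22 higher and 2 lower (median −0.03, mean 0.04, test upward). Neutrophil (Lcn2 by 1.25) and NF-κB lists (Vcam1 by 0.52) had 1 call each, and antigen presentation and female-biased genes 1 higher and 1 lower. Lists with 0 calls were T and NK cells (12 measured), B cells (15), sinusoidal endothelium (18), erythroid (8) and mitochondrial genes (7).

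**Figure D2:**
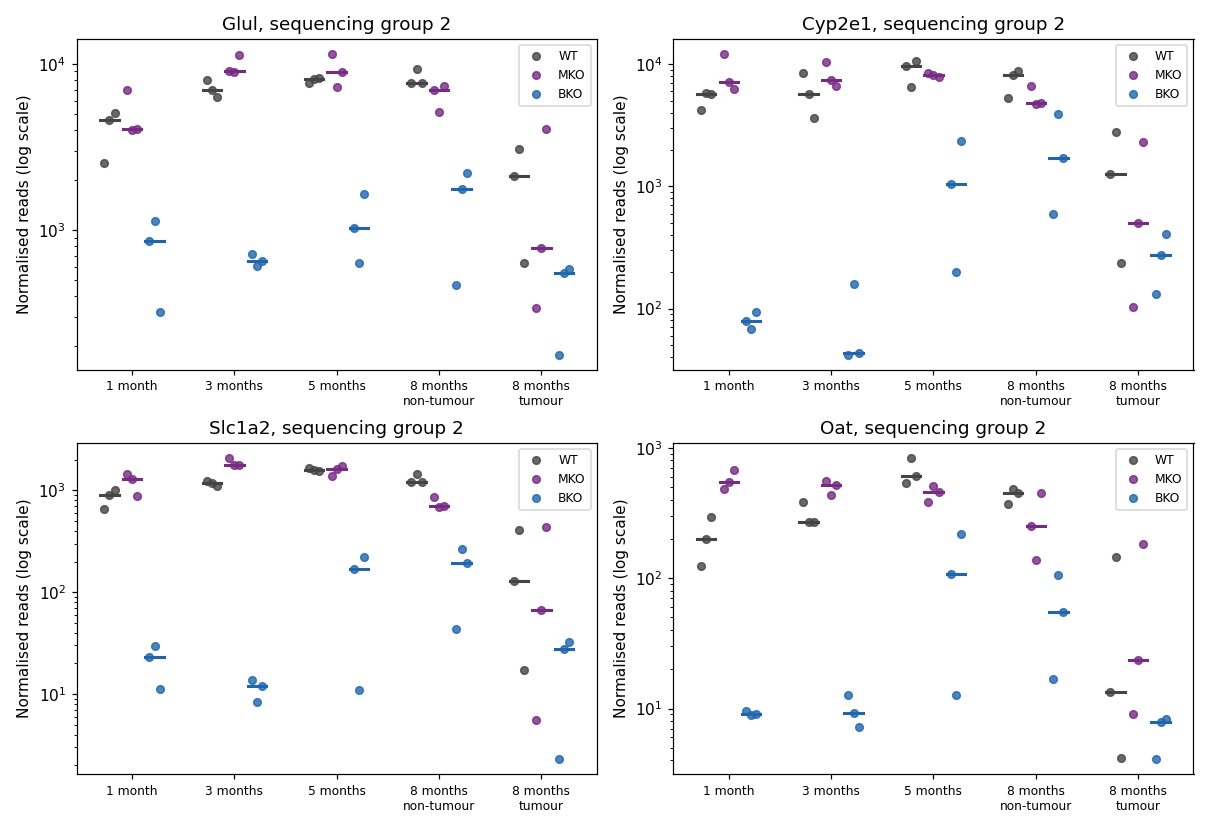
Normalised read counts (log axis) of Glul, Cyp2e1, Slc1a2 and Oat in each library of sequencing group 2 by stage and genotype, with bars at group medians. Cyp2e1 in the 3 BKO libraries of 8-month non-tumour liver was 597.7, 3938.0 and 1711.0, against a WT mean of 7417.

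MKO and WT non-tumour livers were compared to ask what loss of the receptor MET did (12 libraries each), and 351 genes passed, 205 higher and 146 lower. Asns rose by 2.74 ± 0.32 (adjusted p = 1.5e-06), from WT means of 14.21 to 62.97 normalised reads to 175.2 to 641.8 in MKO. The imprinted RNA H19 rose by 2.29 ± 0.49 (adjusted p = 0.00675), Akr1c18, a steroid dehydrogenase, by 1.33 ± 0.34. The calcium-binding gene S100a11 rose by 1.07 ± 0.22, the neurotrophin receptor Ntrk2 by 1.06 ± 0.28 and the kinase Map3k12 by 1.04 ± 0.14. Ppp1r9a fell (−1.19 ± 0.13, adjusted p = 6.99e-07), Mios, a regulator of mTORC1 (−0.97 ± 0.08, adjusted p = 1.62e-10) and the translation repressor Eif4ebp2 (−0.81 ± 0.13, adjusted p = 0.000259). Rgs16 fell (−0.84 ± 0.20), Kyat3 (−0.82 ± 0.21) and Snora30 (−0.82 ± 0.22). Few list members passed: oncofetal genes had 2 of 18 higher (adjusted p = 0.404 with an estimated correlation) and fatty acid oxidation 2 of 22 higher and 1 lower (Hadh by 0.36, Ehhadh by 0.33, Ppara by −0.46). The lists of macrophages (Marco by 0.98), NRF2 (Gsta4 by 0.60), endoplasmic reticulum stress (Asns) and female-biased genes had 1 higher each. Acute phase (Fga by −0.39), p53 (Ei24 by −0.31), cholesterol (Stard4 by −0.39) and male-biased genes (C8a by −0.46) had 1 lower each. Adjusted over the list alone, 5 oncofetal and 6 female-biased genes were higher. Stellate genes had 0 calls of 24 and a median of 0.21 (adjusted p = 0.513 with an estimated correlation), and the other lists held 0 calls. Stage by stage, 744 genes passed at 8 months and 24, 3 and 6 at 1, 3 and 5 months. Same-number MKO and WT libraries at 8 months correlated at 0.12 to 0.3, though the labels do not pair them. With the number as a block 897 genes passed at that stage. The count became 572 from the groups of the comparison alone and 810 with library weights. It was 180, 194, 227 and 231 without WT 8m_NT replicate 1, MKO 5m replicate 1, MKO 8m_NT replicate 2 and MKO 3m replicate 3.

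Whether a knockout's effect differed between stages was tested as an interaction, and each value is the largest change of the effect relative to 1 month. For SKO 736 genes passed, with Mien1 at −1.0 and Snx4 at −0.93, Cd300lg, an endothelial receptor, at 1.56 (adjusted p = 0.000761 each). Cebpd, an acute phase transcription factor, stood at −1.78, Ndufa2 at −0.65 and Slc25a32 at 0.98 (adjusted p = 0.00174 each). For BKO 86 genes passed, with Shld2 at −2.05 (adjusted p = 0.00491), the chaperone Hsph1 at −2.18 and Hddc3 at 2.34 (adjusted p = 0.00745 each). Fam107a stood at −3.21 and Rab30 at 1.26 (adjusted p = 0.0121 each). For MKO 44 genes passed, with Mmrn2, an endothelial matrix gene, at 0.96 (adjusted p = 4.88e-05), Hamp2, a hepcidin, at −5.13 (adjusted p = 0.000274), and Habp4 at −2.34 (adjusted p = 0.000909). Nsd3 stood at −1.25, Pde2a at 0.88 and Plcxd2 at −1.20 (adjusted p = 0.00597 each). For IKO 9 genes passed, with Ube2b at 0.59, Hddc3 at 1.61 and Ppp1r3b, a regulator of glycogen synthesis, at −1.69 (adjusted p = 0.019 each), with Cebpd at −1.61 and Polr2a at 0.70 (adjusted p = 0.0191 each). Hddc3 averaged 43.15, 5.978, 46.79 and 8.245 normalised reads across the 4 stages of WT in sequencing group 1 and 83.55, 8.029, 81.74 and 5.785 in WT of sequencing group 2. The WT level itself thus swung between stages, and this swing enters the Hddc3 interactions of IKO and BKO. The interactions of IKO and SKO used the same WT libraries, so Cebpd, found in both, is not an independent result. Ptpn11, Ikbkb, Met and Ctnnb1 did not pass in any of the 4 tests. Library weights gave 1950, 917, 400 and 196 genes for SKO, BKO, MKO and IKO. Quantile normalization gave 477 for SKO, voom 52 for BKO and the groups of the comparison alone 149 for MKO. Leaving out 1 library gave 481 (WT 1m replicate 2), 486 (SKO 1m replicate 3) and 1177 (SKO 8m_NT replicate 4) for SKO and 11 (WT 1m replicate 2) to 174 (BKO 5m replicate 2) for BKO. It gave 17 (WT 8m_NT replicate 1) to 96 (MKO 8m_NT replicate 1) for MKO and 1 (IKO 1m replicate 3) to 103 (WT 3m replicate 1) for IKO, moving the count over 1.5-fold in 3, 11, 5 and 8 cases.

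Tumours of IKO and WT were compared to ask which tumour transcripts differed with loss of IKK (n = 4 each). Male-biased genes were higher in IKO tumours: Mup17 by 4.72 ± 0.90 (adjusted p = 0.000726), Mup11 by 4.63 ± 1.01, Mup9 by 3.29 ± 0.65, Mup7 by 3.12 ± 0.68 and Hsd3b5 by 3.25 ± 0.82. Ly6k, a GPI-anchored surface gene, rose by 3.31 ± 0.48 (adjusted p = 1.13e-05). Hmgcs1, of cholesterol synthesis, fell (−1.94 ± 0.39, adjusted p = 0.0013), Gpc3, a liver tumour marker (−1.56 ± 0.42, adjusted p = 0.0235). Falls were also seen in Hddc3 (−1.78 ± 0.24), the chemokine Cxcl14 (−1.55 ± 0.36), Trim12a (−1.55 ± 0.23) and Papss1 (−1.47 ± 0.19). The male-biased list had 16 of 20 higher (median 2.06; Cyp7b1 by 2.42, Mup3 by 2.40; adjusted p = 0.225 with an estimated correlation). Pericentral genes had 11 of 22 higher (median 0.70; Cyp2e1 by 1.99, Lhpp by 1.72, Rgn by 1.45; adjusted p = 0.0779 with an estimated correlation), and Cyp2e1 averaged 4920 normalised reads in IKO tumours and 1293 in WT tumours. Single libraries held 2574.2 to 7097.9 in IKO tumours, 651 to 1922.8 in WT tumours and 7294.5 to 10588.2 in 8-month non-tumour WT liver. For Cyp2e1 the IKO tumours thus lay between WT tumours and WT non-tumour liver. Whether loss of IKK itself or another difference between these tumours accounts for this was not tested. Bile acid genes had 8 of 20 higher (Slco1b2 by 1.11, Cyp27a1 by 1.09; adjusted p = 0.225 likewise). Xenobiotic genes had 5 of 22 higher and 2 lower (Cyp2c29 by 2.38, Cyp2c50 by 2.32; adjusted p = 0.453 likewise) and periportal genes 3 of 20 higher (Etnppl by 1.85, Cyp2f2 by 1.57; adjusted p = 0.675 likewise).

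NRF2 targets had 4 of 25 lower in IKO tumours (Slc7a11 by −1.89, Gpx2 by −1.47, Nqo1 by −1.14; adjusted p = 0.665 with an estimated correlation), and 8 adjusted over the list alone. Erythroid genes had 2 of 8 higher (Alas2 by 1.77, Car1 by 0.65; adjusted p = 0.385 likewise) and fatty acid oxidation 2 of 22 higher. Single calls were Krt7 by −0.92 (cholangiocyte), Lox by −0.97 (stellate), Plk2 by −0.52 (p53), Sult2a2 by −1.05 (female-biased), Dlk1 by 1.08 and Gpc3 (oncofetal) and Hmgcs1 (cholesterol). Adjusted over the list alone, 10 of 24 stellate genes were lower and 2 higher (median −0.49; adjusted p = 0.454 likewise). The other lists had 0 calls, ERK targets with a median of −0.27 (adjusted p = 0.385 likewise), acute phase with a median of −0.17, a mean of 0.08 and a downward test, and antigen presentation with a median of 0.02, a mean of −0.03 and an upward test. Of the 467 called genes 321 were higher and 146 lower, and their spread between libraries was 1.34 times as large in tumours as in non-tumour liver. Fitted with the tumour groups alone 35 genes passed, 33 of them among the 467. Leaving out 1 library gave 191 (WT 8m_T replicate 3), 232 (IKO 8m_T replicate 4), 252 (IKO 8m_T replicate 1) or 261 (WT 8m_T replicate 2).

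SKO tumours were compared with WT tumours for the same question on SHP2 (n = 4 each), and 223 genes passed, 88 higher and 135 lower. The axonemal dynein Dnah2 rose by 2.10 ± 0.19 and the von Willebrand factor protease Adamts13 by 2.09 ± 0.19 (adjusted p = 1.65e-11 each). Cd5l, a macrophage gene, rose by 1.57 ± 0.36 (adjusted p = 0.00819), Pebp1 by 1.43 ± 0.18 (adjusted p = 2.68e-07). The guanylate cyclase Gucy2c rose by 1.40 ± 0.31 and Akr1b7 by 1.39 ± 0.26. The ribosomal protein gene Rpl29 fell (−2.63 ± 0.33, adjusted p = 2.13e-07), Psg18 (−2.32 ± 0.27), the lipogenic regulator Thrsp (−2.05 ± 0.45), Hmgcs1 (−1.95 ± 0.39), Mup3 (−1.91 ± 0.51) and Fbxw15 (−1.85 ± 0.27). IKO and SKO tumours were compared with the same WT tumours, so calls found in both, as of Hmgcs1, are not independent. Macrophage markers had 4 of 21 higher (median 0.71; Vsig4 by 1.06, Timd4 by 0.80; adjusted p = 0.304 with an estimated correlation), and 12 adjusted over the list alone. Erythroid genes had 2 of 8 higher (Hba-a2 by 1.14; adjusted p = 0.205 likewise). Periportal genes had 3 of 20 lower (G6pc by −1.58, Sds by −1.35, Pigr by −1.26; adjusted p = 0.543 likewise) and lipogenesis 2 of 25 lower (Gpam by −0.83; adjusted p = 0.375 likewise). Cholesterol synthesis had 1 of 22 lower, and 10 adjusted over the list alone (median −0.56; adjusted p = 0.383 likewise). NRF2 targets had 2 of 25 higher (G6pdx by 1.10, Hmox1 by 0.88; median −0.04, mean 0.03). Oncofetal calls were Dlk1 by 0.94 and Spink1 by −1.35, and acute phase genes had a median of −0.04 and a mean of 0.01. With the tumour groups alone 33 genes passed, 32 of them among the 223 and 60.6% higher in place of 39.5%. Library weights gave 112. The count was 108 without WT 8m_T replicate 2, 130 without WT 8m_T replicate 3 and 357 without WT 8m_T replicate 4.

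BKO tumours were compared with WT tumours (n = 3 each), and 71 genes passed, 50 higher and 21 lower. Limd1, a LIM-domain gene, fell (−2.82 ± 0.18, adjusted p = 1.72e-13) and H19 (−4.19 ± 0.98, adjusted p = 0.0352). Adrb3 fell (−2.30 ± 0.35), Nxpe2 (−1.79 ± 0.40), Plekhb1 (−1.64 ± 0.36) and the proteasome gene Psma8 (−1.42 ± 0.30). The lysophosphatidic acid receptor Lpar3 rose by 1.79 ± 0.21 (adjusted p = 1.43e-06), the immunoglobulin gene Iglc3 by 1.85 ± 0.30 (adjusted p = 0.00106). The matrix gene Mgp rose by 1.74 ± 0.43, the protease receptor F2rl1 by 1.62 ± 0.37, the phagocyte oxidase Cybb by 1.52 ± 0.35 and Col4a4 by 1.51 ± 0.35. Stellate genes had 4 of 24 higher and 1 lower (Dcn by 1.44, Mmp2 by 1.38, Bgn by 0.98; adjusted p = 0.58 with an estimated correlation). Antigen presentation had 2 of 18 higher (H2-K1 by 0.83, H2-D1 by 0.75; adjusted p = 0.304 likewise), and 10 adjusted over the list alone. B cell (Ighm by 1.61, Iglc2 by 1.53; adjusted p = 0.304 likewise) and cholangiocyte genes (Krt7 by 1.29, Krt19 by 1.11; adjusted p = 0.359 likewise) had 2 higher each, and Orm1 was higher by 1.82 among acute phase genes. Pericentral genes had 0 calls of 22 and a median of −0.65 (adjusted p = 0.375 likewise), with Glul at −1.97 ± 0.58 (adjusted p = 0.119), and 5 were lower adjusted over the list alone. Macrophage markers had 0 calls and a median of 0.53, oncofetal genes a median of 0.04 and a mean of −0.17, and lipogenesis a median of −0.02 and a mean of 0.00, and the lists not named here had 0 calls. With the tumour groups alone 1 gene passed, Limd1, library weights gave 27, and the count was 15 without BKO 8m_T replicate 2. Called genes varied 1.65 times as much between tumours as between non-tumour livers, and groups of 3 fail to overlap by chance in 10% of cases.

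MKO tumours were compared with WT tumours (n = 3 each), and 523 genes passed, 388 higher and 135 lower. Cxcl14, a chemokine, rose by 2.80 ± 0.50 (adjusted p = 0.00153), Mgp by 2.71 ± 0.43 (adjusted p = 0.000305) and Asns by 2.38 ± 0.64. The steroid hydroxylase Cyp21a1 rose by 2.28 ± 0.45, the acute phase gene Orm1 by 2.06 ± 0.45 and the peptide hormone Apela by 2.01 ± 0.33. H19 fell (−4.01 ± 0.98, adjusted p = 0.0161), Hmgcs1 (−2.26 ± 0.48, adjusted p = 0.00611), Adrb3 (−1.99 ± 0.35), Kyat3 (−1.93 ± 0.41), Prom2 (−1.89 ± 0.31) and the glycosyltransferase Galnt6 (−1.62 ± 0.36). BKO and MKO tumours were compared with the same WT tumours, so calls found in both, as of H19 and Adrb3, are not independent. Macrophage markers had 13 of 21 higher (median 1.31; Trem2 by 1.84, Cd68 by 1.47, C1qc by 1.33; adjusted p = 0.205 with an estimated correlation). Cholesterol synthesis had 10 of 22 lower (median −0.86; Cyp51 by −1.37, the regulator Srebf2 by −0.89; adjusted p = 0.205 with an estimated correlation), and 20 adjusted over the list alone. Stellate genes had 5 of 24 higher (Dcn by 1.97, Loxl1 by 1.51, Bgn by 1.46; adjusted p = 0.354 with an estimated correlation). Interferon genes had 3 of 23 higher (Oasl2 by 1.10, Oas2 by 0.95, Irf7 by 0.86; adjusted p = 0.375 likewise) and antigen presentation 3 of 18 (H2-Eb1 by 1.54, H2-Ab1 by 1.46, H2-DMa by 1.11; adjusted p = 0.513 likewise). Proliferation genes had 2 of 29 lower (Ccnb2 by −0.82, Rrm2 by −0.63; adjusted p = 0.513 likewise).

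Cholangiocyte genes had 2 of 14 higher in MKO tumours (Krt7 by 1.40, Krt19 by 1.08), as had NRF2 (Gstm1 by 1.06, Pgd by 0.70), p53 (Ddit4l by 0.89) and xenobiotic genes (Gadd45b by 1.04, Cyp1b1 by 0.87). Adjusted over the list alone, 12 NRF2 genes were higher (adjusted p = 0.383 with an estimated correlation). Single calls were Ctsc by 0.86 (periportal), Flt4 by 1.02 (sinusoidal endothelium), Nfkbie by 0.92 (NF-κB), Cd36 by 1.10 (lipogenesis), and Hk2 by 0.67 (glycolysis, median −0.08, mean 0.01). Lower calls were Hadhb by −0.61 (fatty acid oxidation, median −0.15, mean 0.08, test downward), Serpina1e by −1.66 (male-biased) and Pdia4 by −0.73 (endoplasmic reticulum stress). The oncofetal list had a median of 0.11, a mean of −0.10 and an upward test, with H19 called. Pericentral genes had 0 calls of 22 (median −0.42), and their levels differed between tumours of 1 genotype. Cyp2e1 held 102.7, 505.4 and 2316.6 normalised reads in MKO 8m_T replicates 1 to 3 and 1266.4, 2812.1 and 234.3 in WT, and Glul 342.6, 777.2 and 4075.3 in MKO and 2108.8, 3058 and 638.9 in WT. T and NK cells, B cells, neutrophils, erythroid, bile acid, female-biased, ERK and mitochondrial lists also had 0 calls. With the tumour groups alone 0 genes passed, beside 2212 with unadjusted p below 0.05 in the fit of all groups, and library weights gave 207. Called genes varied 1.43 times as much between tumours as between non-tumour livers. The count was 117 without MKO 8m_T replicate 1, 244 without MKO 8m_T replicate 2, 346 without WT 8m_T replicate 3 and 786 without MKO 8m_T replicate 3.

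**Figure D3:**
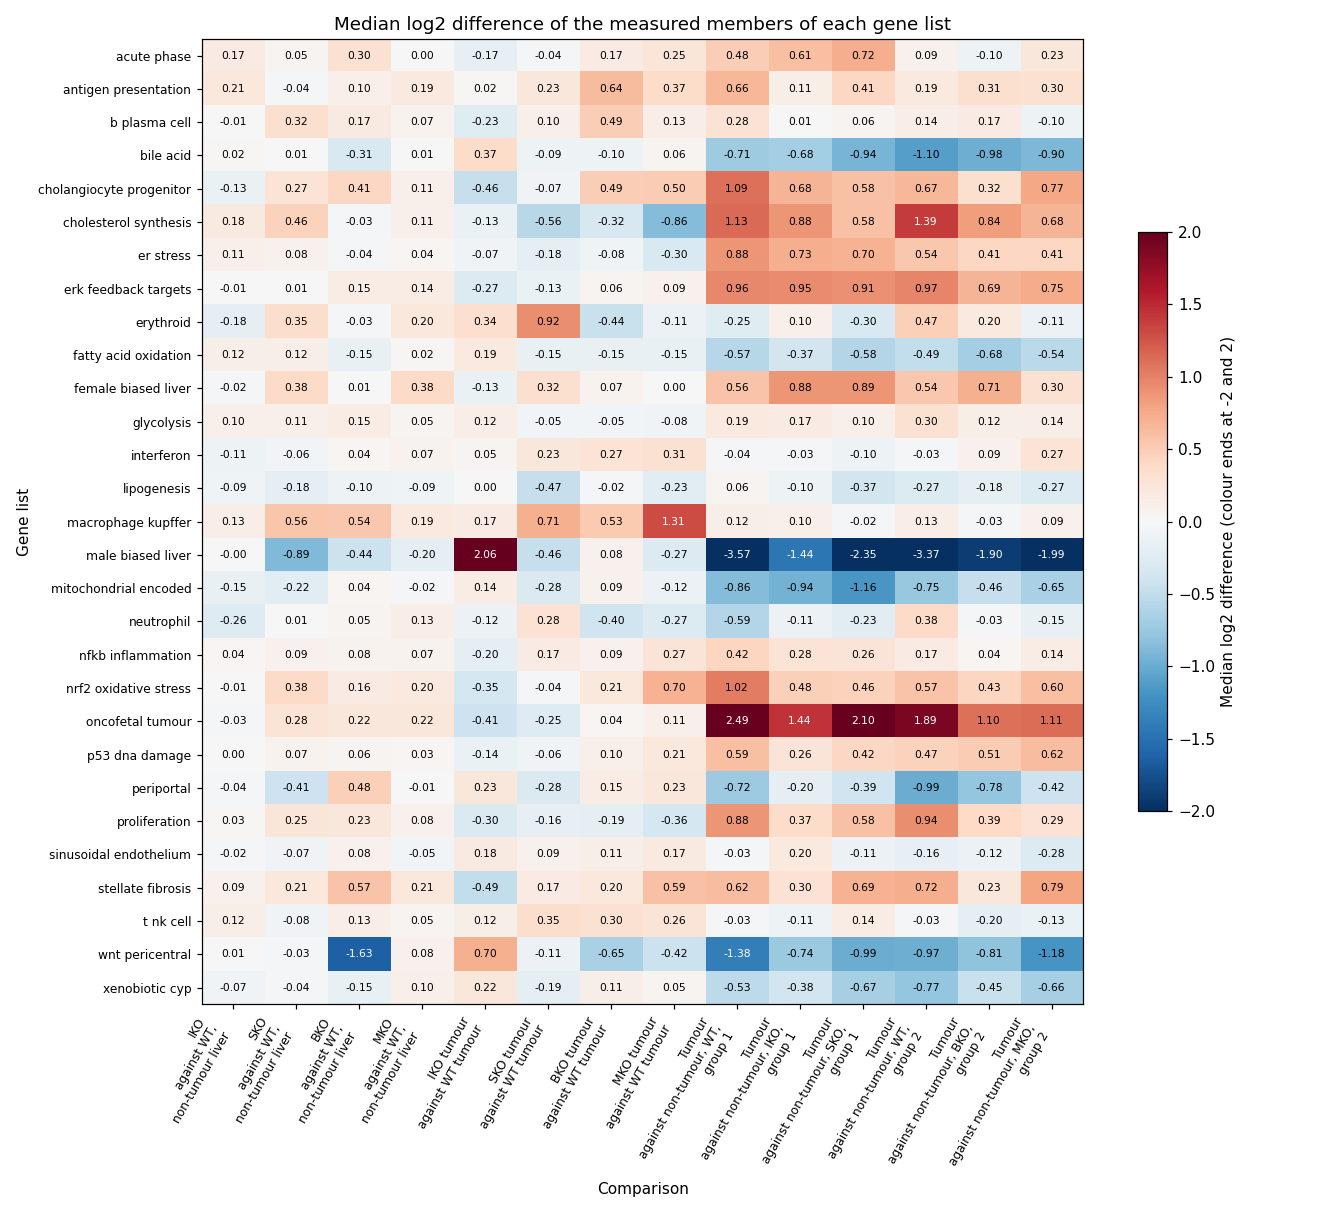
Median log2 difference of each of the 29 gene lists (vertical axis) in 14 comparisons (horizontal axis), as colour from −2 to 2. Pericentral genes had a median of −1.63 in BKO non-tumour liver and 0.70 in IKO tumours.

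Tumours were compared with the non-tumour liver of the same age to describe the tumour state, first in WT of sequencing group 1 (n = 4 each), where 2970 genes were higher and 2490 lower. The female-biased cytochrome Cyp2a4 rose by 6.32 ± 0.78 (adjusted p = 2.93e-09), Igfbp1, which binds insulin-like growth factors, by 5.24 ± 0.64. The oncofetal glypican Gpc3 rose by 5.05 ± 0.42 (adjusted p = 5.59e-14), Elapor1 by 4.99 ± 0.41, Ly6d by 4.98 ± 0.54 and Akr1c18 by 4.96 ± 0.60. Mup17 fell (−6.31 ± 0.90, adjusted p = 8.81e-08), Mup11 (−6.001 ± 1.01), Mup1 (−4.91 ± 0.55), Hsd3b5 (−4.83 ± 0.82) and the fatty acid hydroxylases Cyp4a12b (−4.85 ± 0.71) and Cyp4a12a (−4.76 ± 0.63). Ctnnb1 rose by 1.34 ± 0.14 (adjusted p = 2.85e-11). Pericentral genes had 19 of 22 lower (Cyp1a2 by −3.76, Glul by −3.12, Rgn by −3.04; adjusted p = 0.122 with an estimated correlation) and male-biased genes 17 of 20 lower (median −3.57; adjusted p = 0.375 likewise). ERK targets had 15 of 18 higher (Dusp5 by 2.64, Ier3 by 2.54, Spred2 by 1.18; adjusted p = 0.109 likewise) and proliferation genes 21 of 29 (Ccna2 by 2.22; adjusted p = 0.375 likewise). Cholesterol synthesis had 17 of 22 higher (Sqle by 2.85; adjusted p = 0.513 likewise) and oncofetal genes 10 of 18 (Spink1 by 3.94; adjusted p = 0.304 likewise). Bile acid genes had 11 of 20 lower and 2 higher (Slco1b2 by −3.39; adjusted p = 0.173 likewise), and all 7 mitochondrially encoded genes measured were lower (ND4 by −1.55, ND5 by −1.17; adjusted p = 0.398 likewise).

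Stellate genes had 16 of 24 higher and 2 lower in these WT tumours (Col1a1 by 3.43), cholangiocyte genes 10 of 14 higher (Prom1 by 2.697) and p53 targets 12 of 22 higher and 1 lower (Btg2 by 3.30). NRF2 targets had 13 of 25 higher and 2 lower (Cbr3 by 3.39) and endoplasmic reticulum stress genes 12 of 19 higher (Trib3 by 2.28). Periportal genes had 11 of 20 lower and 4 higher (Etnppl by −2.95, Cps1 by −1.80), xenobiotic genes 11 of 22 lower and 4 higher (Cyp2c50 by −3.68) and fatty acid oxidation 11 of 22 lower and 4 higher (Cpt2 by −0.92, Cpt1a by 1.27). With an estimated correlation the smallest adjusted p of these 8 lists was 0.354. NF-κB genes had 9 of 21 higher and 1 lower (Relb by 1.20, Sod2 by −0.80), antigen presentation 9 of 18 higher and 2 lower (H2-T23 by 1.26) and female-biased genes 6 of 13 higher (Abcd2 by 3.50). Lipogenesis had 7 of 25 higher and 5 lower (Fads2 by 2.44) and acute phase genes 8 higher and 8 lower of 25 (Il1rn by 2.78, Crp by −1.47). Glycolysis had 4 of 16 higher and 2 lower (Ldha by 1.26). Macrophage markers had 5 higher and 4 lower of 21 (Mpeg1 by 1.51, Cd163 by −0.96) and sinusoidal endothelium 4 and 3 of 18 (Stab1 by 0.84, Rspo3 by −1.15). Neutrophil genes had 1 higher and 5 lower of 10 (Lcn2 by 4.03, Elane by −1.34) and erythroid genes 0 and 3 of 8 (Alas2 by −3.32). B cells had 2 and 1 of 15, T and NK cells 0 and 1 of 12 (Cd4 by −0.92) and interferon genes 2 and 2 of 23 (Oas1a by 1.19).

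The second WT set (n = 3 each) had 1949 genes higher and 1561 lower in tumours. H19 rose by 5.69 ± 0.98 (adjusted p = 4.03e-05), Cyp2a4 by 5.22 ± 0.83, Akr1c18 by 5.18 ± 0.67, Igfbp1 by 5.15 ± 0.72, Elapor1 by 4.58 ± 0.45 and Gpc3 by 4.24 ± 0.44. Mup11 fell (−6.62 ± 1.60), Mup17 (−6.40 ± 1.31), Cyp4a12a (−5.29 ± 1.07), Cyp4a12b (−4.94 ± 1.02), Cyp2c29 (−4.55 ± 0.65) and Nnmt (−4.39 ± 0.78). Lower were 17 of 20 male-biased, 14 of 22 pericentral and 13 of 20 bile acid genes. Higher were 24 of 29 proliferation, 18 of 22 cholesterol synthesis, 13 of 18 ERK target and 10 of 18 oncofetal genes. In this order their lists had adjusted p = 0.383, 0.481, 0.354, 0.359, 0.36, 0.302 and 0.24 with an estimated correlation. List medians and tests differed in sign for macrophages (0.13, mean −0.19), erythroid (0.47, mean 0.10) and acute phase genes (0.09, mean −0.26), whose tests pointed down. Across 12966 genes the tumour effects of both WT sets had a Pearson r of 0.848, with 1418 genes higher in both (446 expected), 1148 lower in both (300 expected) and 12 opposite (732 expected). No p is given, because genes are not independent. From the groups of the comparison alone 1741 genes passed, 1712 of them among the 3510.

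IKO tumours differed from IKO non-tumour liver in 4319 genes, 2364 higher and 1955 lower (n = 4 each), with Igfbp1 up by 4.92 ± 0.64, Cyp2a4 by 4.72 ± 0.78 and Akr1c18 by 4.29 ± 0.60. Mup12 was lower (−2.74 ± 0.46), Mup1 (−2.56 ± 0.55) and the carrier Slco1b2 (−2.08 ± 0.22). SKO tumours differed in 5148 genes, 2726 higher and 2422 lower (n = 4 each), with Igfbp1 up by 5.40 ± 0.64, Cyp2a4 by 4.66 ± 0.78 and Lcn2, a neutrophil and acute phase gene, by 4.47 ± 0.70. Cyp4a12a was lower (−4.40 ± 0.63), Cyp7a1 (−4.19 ± 0.46) and Cyp4a14 (−4.17 ± 0.85). Pericentral genes were lower, 14 of 22 in IKO and 16 in SKO, as were male-biased genes, 12 and 14 of 20, bile acid genes, 13 and 12 of 20, and mitochondrial genes, 5 and 7 of 7. ERK targets were higher, 14 of 18 in IKO and 12 in SKO (adjusted p = 0.122 with an estimated correlation in both), with Dusp4 by 1.24 in IKO and 1.48 in SKO. Proliferation genes were higher, 9 and 16 of 29, as were oncofetal genes, 11 and 12 of 18, and cholesterol synthesis, 15 and 11 of 22. Median and mean differed in sign for neutrophils (−0.11 and 0.23 in IKO, −0.23 and 0.16 in SKO) and interferon genes (−0.03 and 0.05 in IKO, −0.10 and 0.03 in SKO), and in IKO for erythroid (0.10 and −0.17) and lipogenesis genes (−0.10 and 0.11).

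BKO tumours differed from BKO non-tumour liver in 1907 genes, 1088 higher and 819 lower (n = 3 each), with Wfdc15b up by 3.33 ± 0.49 (adjusted p = 5.34e-05), Lcn2 by 3.22 ± 0.79 and Ocstamp by 2.98 ± 0.47. Cyp4a12a was lower (−3.39 ± 1.07), Nnmt (−3.26 ± 0.78) and Slco1a1 (−3.26 ± 0.91). Bile acid genes had 11 of 20 lower and 1 higher, male-biased genes 10 of 20 and pericentral genes 8 of 22 lower (Cyp2e1 by −2.56). Cholesterol synthesis had 11 of 22 higher, ERK and p53 targets 9 each (Ier3 by 1.83, Phlda3 by 1.48), oncofetal genes 9 of 18 and proliferation genes 5 of 29. The smallest adjusted p of these lists was 0.304 with an estimated correlation. Mitochondrial genes had 0 calls, and neutrophil (median −0.03, mean 0.30) and erythroid lists (median 0.20, mean −0.20) differed in sign. Same-number tumour and non-tumour BKO libraries correlated at 0.23 to 0.33 in 3 of 3 pairs, though the labels do not pair them. With the replicate block 924 genes passed. From the groups of the comparison alone 12 genes passed, and the count was 780, 926 and 972 without BKO 8m_NT replicate 2, BKO 8m_NT replicate 3 and BKO 8m_T replicate 1.

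MKO tumours differed from MKO non-tumour liver in 2245 genes, 1265 higher and 980 lower (n = 3 each), with Gpc3 up by 3.81 ± 0.44 (adjusted p = 1.81e-06), Lcn2 by 3.80 ± 0.79 and Ly6d by 3.67 ± 0.61. Cyp2c37 was lower (−3.57 ± 0.53), Cyp2c50 (−3.47 ± 0.72), the esterase Ces3a (−3.44 ± 0.63) and Cyp2e1 (−3.29 ± 0.74). Stellate genes had 14 of 24 higher (Acta2 by 2.13, Col4a1 by 1.80), ERK targets 13 of 18 (Ier3 by 2.12, Etv4 by 1.47), p53 targets 12 of 22 (Psrc1 by 2.48, Phlda3 by 1.97). Oncofetal genes had 8 of 18, cholangiocyte genes 6 of 14, cholesterol synthesis 5 of 22 and proliferation 1 of 29, the last Ccne1 by 0.75. Pericentral and male-biased genes had 13 lower each (Notum by −1.21, Susd4 by −2.67), bile acid genes 12 lower and 1 higher, and mitochondrial genes 2 lower. The smallest adjusted p of these lists was 0.225 with an estimated correlation. Medians and means differed in sign for B cells (−0.10 and 0.08), neutrophils (−0.15 and 0.23) and macrophages (0.09 and −0.05). From the groups of the comparison alone 82 genes passed and with the replicate block 1151. The count was 1034, 1239, 1376 and 1401 without MKO 8m_T replicate 1, MKO 8m_NT replicate 3, MKO 8m_T replicate 2 and MKO 8m_NT replicate 1.

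Whether a knockout changed the tumour effect itself was tested as the difference of tumour and non-tumour liver between knockout and WT. In IKO 14 genes had a higher and 2 a lower value, with Slc1a2 at 2.62 ± 0.58 (adjusted p = 0.0322), Cyp7b1, of bile acid synthesis, at 2.59 ± 0.54, and Lhpp at 2.15 ± 0.39 (adjusted p = 0.00747). The proline dehydrogenase Prodh stood at 2.11 ± 0.44 and Hddc3 at −1.62 ± 0.34. Of pericentral genes 3 of 22 were higher, Slc1a2, Lhpp and Rgn at 1.49 ± 0.34, and 11 adjusted over the list alone (adjusted p = 0.0831 with an estimated correlation). Of male-biased genes 1 of 20 was higher, and 14 adjusted over the list alone (median 2.04; adjusted p = 0.304 with an estimated correlation). In MKO 5 genes had a higher and 12 a lower value, with Cyp21a1 at 3.48 ± 0.63, Tmem150c at 1.54 ± 0.29, Gucy1a1 at 1.14 ± 0.23, and Tacc1 at 1.11 ± 0.23. Lower values were H19 at −6.32 ± 1.39 (adjusted p = 0.0445), Adrb3 at −2.698 ± 0.49, Prom2 at −2.41 ± 0.44 and Fmn1 at −1.95 ± 0.33. Proliferation genes had 0 of 29 called there, and 11 lower adjusted over the list alone (median −0.65; adjusted p = 0.334 with an estimated correlation). In BKO 4 genes passed, the matrix gene Reln at −2.32 ± 0.38, Fmn1 at −1.97 ± 0.33, Limd1 at −1.49 ± 0.25 and Dpy19l3 at 2.03 ± 0.40. In SKO 4 genes passed, Dnah2 at 1.40 ± 0.27 (adjusted p = 0.0164), Psg18 at −1.93 ± 0.38, Hddc3 at −1.84 ± 0.34 and Gm4841 at 2.26 ± 0.42, and every list had 0 calls. Gm4841 was chosen after its values were seen. Knockouts of a sequencing group shared their WT libraries, so genes found in both, as Hddc3 and Fmn1, are not independent results. With the replicate block the counts were 0, 0, 0 and 1 for IKO, MKO, BKO and SKO, beside 1081, 1353, 919 and 1443 genes with unadjusted p below 0.05. From the groups of the comparison alone they were 9, 0, 0 and 1. Leaving out 1 library gave 3 (IKO 8m_T replicate 1) to 84 (IKO 8m_T replicate 2) genes in IKO, 8 (MKO 8m_T replicate 1) to 137 (WT 8m_T replicate 2) in MKO. It gave 2 (BKO 8m_NT replicate 2) to 26 (WT 8m_T replicate 2) in BKO and 2 (WT 8m_NT replicate 1) to 48 (SKO 8m_NT replicate 4) in SKO, moving the count over 1.5-fold in 13, 6, 5 and 10 cases.

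Age was compared in WT as 8-month non-tumour against 1-month liver. All mice were DEN-treated and tumours were present at 8 months. Age therefore cannot be told apart here from time since treatment or from the state of a tumour-bearing liver. In sequencing group 1 (n = 4 each) 517 genes were higher and 391 lower, with Moxd1 up by 3.85 ± 0.61 (adjusted p = 3.96e-05), Mup17 by 3.43 ± 0.90, Fitm1, a lipid droplet gene, by 3.12 ± 0.42 and Mup1 by 2.99 ± 0.55. Hamp2 was lower (−5.14 ± 0.94, adjusted p = 0.000338), Col1a1 (−2.12 ± 0.47), Hsd17b6 (−1.93 ± 0.50) and elastin, Eln (−1.65 ± 0.30). Interferon genes had 5 of 23 lower (Usp18 by −1.35, Oasl2 by −0.97), and 11 adjusted over the list alone (adjusted p = 0.304 with an estimated correlation). Stellate genes had 6 of 24 lower (Col1a2 by −1.55, Col3a1 by −0.98; adjusted p = 0.58 likewise). Antigen presentation had 3 of 18 lower (H2-T23 by −1.30; adjusted p = 0.383 likewise), and endoplasmic reticulum stress genes 3 of 19 higher (Hsp90b1 by 0.85; adjusted p = 0.55 likewise). In sequencing group 2 (n = 3 each) 120 genes were higher and 103 lower, with Moxd1 up by 3.92 ± 0.87, C4a, of complement, by 3.22 ± 0.54, Mup9 by 3.17 ± 0.75 and Fitm1 by 3.10 ± 0.83. Hamp2 was lower (−5.85 ± 0.77, adjusted p = 4.2e-05), Hddc3 (−2.04 ± 0.33), Igf2bp3 (−2.02 ± 0.25) and Dnai1 (−1.84 ± 0.50). The level of Hddc3 did not fall steadily with age, since its WT means given above were low at 3 months and high again at 5 months. Interferon genes had 3 of 23 lower (Usp18 by −1.14, Oasl2 by −1.10; adjusted p = 0.284 likewise), and 12 adjusted over the list alone. The groups of the comparison alone gave 511 and 82 genes and library weights 1714 and 840. The count in sequencing group 1 was 485, 503, 511 and 579 without WT 8m_NT replicate 1, WT 1m replicate 4, WT 1m replicate 3 and WT 8m_NT replicate 2. Leaving out any of the 6 libraries in sequencing group 2 gave 37 (WT 1m replicate 2) to 146 (WT 8m_NT replicate 1).

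Over the 580 pairs of list and comparison, 0 passed with an estimated correlation, 233 passed with the preset correlation of 0.01 and 2 passed after quantile normalization. All list counts above describe called members.

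Knockouts were compared with each other to ask whether their non-tumour effects ran together. IKO and SKO effects had r = 0.286, with 141 genes higher in both (60.2 expected), 274 lower in both (72.9 expected) and 30 opposite (135 expected). The pair shared its WT libraries, and 20 simulations with shared WT libraries and no effect gave a mean r of 0.527 (highest 0.7) and 0 genes called in both in the same direction. Shared libraries add the same covariance with or without effects, so covariances and not r were compared, 0.013 observed and 0.0054 simulated. Over 20 splits with separate WT libraries for each knockout r was 0.182 (0.046 to 0.268). BKO and MKO, which also shared WT libraries, had r = 0.336, with 82 genes higher in both (21.6 expected), 64 lower in both (13.2 expected) and 9 opposite (33.9 expected). Its covariance was 0.016 against a simulated 0.0068 (simulated r 0.541), with 0 such genes in simulations, and its 3 WT libraries per stage were too few to split, so part of the overlap can come from them. Across sequencing groups SKO and MKO had r = 0.394, with 42 genes higher in both (24.6 expected), 71 lower in both (15.9 expected) and 6 opposite (39.8 expected). Asns was among those higher in both. WT libraries of both sequencing groups may come from the same animals, as described below. Pairs across sequencing groups may therefore share WT deviations as well, which would add to their r and overlaps. SKO and BKO had r = 0.213, with 292 higher in both (164 expected), 308 lower in both (128 expected) and 209 opposite (289 expected). IKO and MKO had r = 0.099, with 6 higher in both (7.94 expected), 33 lower in both (7.54 expected) and 11 opposite (16.2 expected), and IKO and BKO r = 0.079, with 43, 113 and 80 genes (52.96, 60.6 and 116 expected). With the effects of the pair taken from different stages the mean r was 0.181 for SKO and MKO, 0.12 for SKO and BKO, 0.094 for BKO and MKO, 0.073 for IKO and SKO, −0.006 for IKO and MKO and −0.012 for IKO and BKO. Single choices of stages ranged, in the same order, from 0.026 to 0.353, −0.002 to 0.242 and −0.062 to 0.327. For the last 3 pairs they ranged from −0.1 to 0.172, −0.133 to 0.091 and −0.068 to 0.063.

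Genes near each targeted locus were counted because several of the largest changes lay there. Asns and Mios lay at −9.79 and −9.25 Mb from Met in MKO, and Pebp1 and Acad10 at −3.85 and 0.49 Mb from Ptpn11 in SKO. Rnf170 and Defb1 lay at 3.46 and −0.88 Mb from Ikbkb in IKO, and Limd1 and Fyco1 at 2.55 and 2.86 Mb from Ctnnb1 in BKO. In BKO non-tumour liver Limd1 fell by 1.31 (adjusted p = 7.62e-13). Within 10 Mb of the locus 22 of 85 genes were called in IKO (25.9%, against 8.88% elsewhere), 58 of 196 in SKO (29.6%, against 22.8%), 32 of 89 in BKO (36.0%, against 19.4%) and 4 of 33 in MKO (12.1%, against 2.63%).

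**Figure D4:**
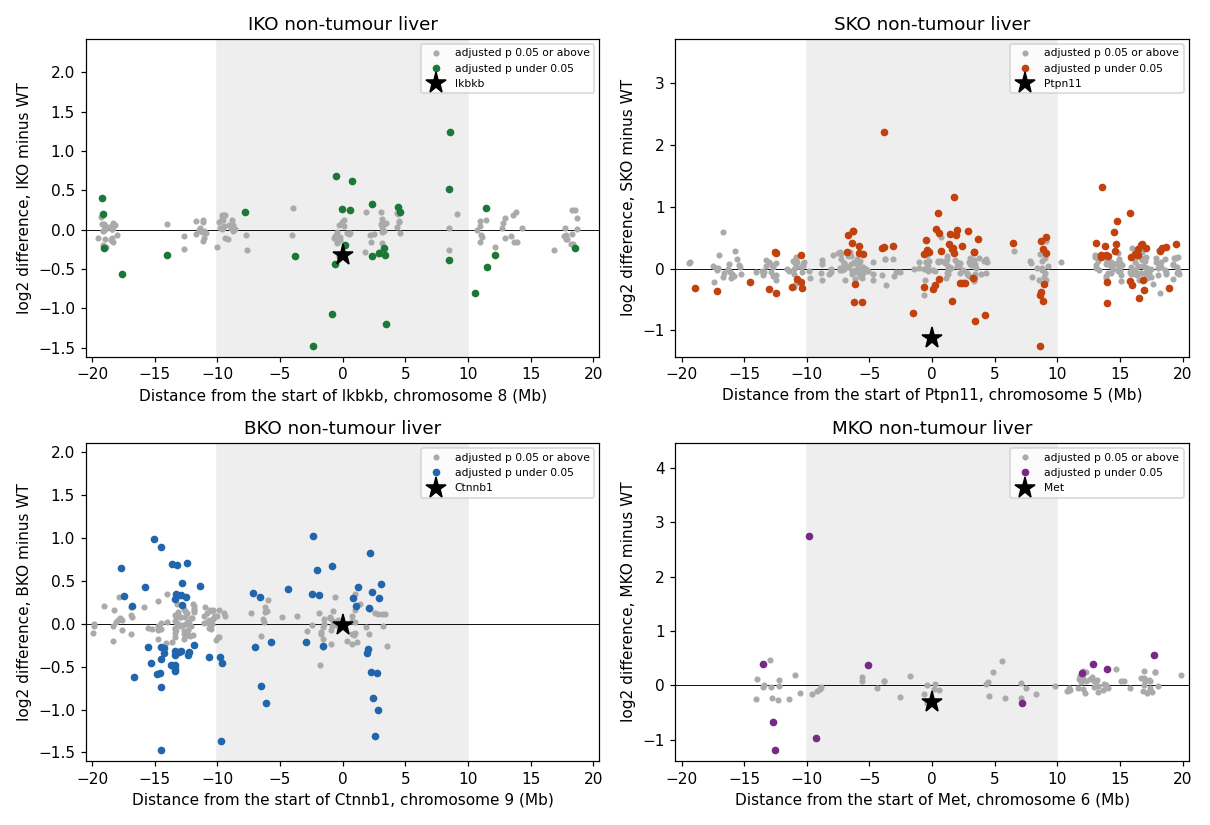
Log2 difference of each gene near the targeted locus in the 4 knockouts by distance in megabases, with called genes marked. In BKO 32 of 89 genes within 10 Mb were called and in MKO 4 of 33.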

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

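The tests of the 3 patterns and of other splits were chosen after the results they examine were seen, while the interactions and the differences of tumour effect were fixed before. The first pattern was the number of called genes near each targeted locus. One hypothesis is that strain variants carried along with the targeted locus changed neighbouring genes or their measurement. Without the genes seen before the count (Rnf170 and Defb1, Pebp1 and Acad10, Limd1 and Fyco1, Asns and Mios), windows elsewhere reached as high a share of called genes in 0.331% of cases for IKO, 0.847% for BKO and, on only 2 of 31 genes, 3.01% for MKO, which is in line with it, while 11.8% for SKO leaves it undecided. Fut10, named above among the IKO rises, lies 8.53 Mb from Ikbkb and was not left out. Of the called genes near the locus 90.9% had the same sign in tumours in IKO (82.3% of other calls), 70.7% in SKO (63.3%), 93.8% in BKO (72.0%) and 4 of 4 in MKO (68.8%). Mios, Pebp1, Limd1 and Rnf170 lie in these windows, so their changes may not follow from loss of the targeted gene. The same holds for Defb1 and Fut10 in IKO, Asl in SKO, Sds in SKO tumours and Cx3cr1 in BKO. Asns lies near Met as well, but it also rose by 2.63 in SKO, whose locus is on chromosome 5.

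The second pattern was the library labelled SKO 3m replicate 2, which lacked the SKO difference. Along that difference, with WT at 0 and SKO at 1, it scored 0.07 over genes on other chromosomes, while the other SKO libraries of that stage scored 0.65 to 0.90. A swap with a WT 3-month library is unlikely, since the highest WT score was 0.29 and no WT library looked like SKO. A WT animal under an SKO label is unlikely, since its score near Ptpn11 was 0.71 against −0.12 to 0.12 in WT, and its Pebp1 held 2595.5 normalised reads against 419.9 to 1076.4. An animal of the SKO line without deletion of Ptpn11 is in line with 0.07, with the score near the locus and with its Ptpn11 of 375.1.

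The third pattern was that WT libraries of both sequencing groups deviated together from their stage means. Of 12 non-tumour WT libraries in sequencing group 2, 10 had a WT partner in sequencing group 1 whose correlation lay above every IKO and SKO library, which is in line with the same WT animals in both sequencing groups. Libraries handled together across genotypes are unlikely as the cause, since the highest IKO or SKO correlation was 0.23 and the best WT partners reached 0.21 to 0.63. Handling shared by WT libraries alone would not show in this comparison and was not tested. In tumours the best partners reached 0.14 to 0.46 and IKO or SKO libraries 0.31. If the animals were shared, comparisons across sequencing groups, including the correlation of the WT tumour effects, were not independent.

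An unusual value by Dixon's test was Met in SKO 8m_T replicate 3, 127.8 normalised reads and the lowest of 4, the single such value in 75 tests, each of the depth or a targeted gene in a group of 4. The other results here were marked because a test found that an effect differed between stages or between genotypes. The stage interaction of IKO had 9 genes, with Ube2b at 0.59, Hddc3 at 1.61, Ppp1r3b at −1.69, Cebpd at −1.61 and Polr2a at 0.70. That of SKO had 736, with Mien1 at −1.0, Snx4 at −0.93, Cd300lg at 1.56, Cebpd at −1.78, Ndufa2 at −0.65 and Slc25a32 at 0.98. That of BKO had 86, with Shld2 at −2.05, Hsph1 at −2.18, Hddc3 at 2.34, Fam107a at −3.21 and Rab30 at 1.26. That of MKO had 44, with Mmrn2 at 0.96, Hamp2 at −5.13, Habp4 at −2.34, Nsd3 at −1.25, Pde2a at 0.88 and Plcxd2 at −1.20. Cebpd in IKO and SKO is not an independent result, because both interactions used the same WT libraries. The difference of tumour effect had 16 genes in IKO, with Slc1a2 at 2.62, Cyp7b1 at 2.59, Lhpp at 2.15, Prodh at 2.11 and Hddc3 at −1.62. In SKO it had 4, with Dnah2 at 1.40, Psg18 at −1.93 and Hddc3 at −1.84. In BKO it had 4, with Dpy19l3 at 2.03, Reln at −2.32, Fmn1 at −1.97 and Limd1 at −1.49. In MKO it had 17, with Cyp21a1 at 3.48, Tmem150c at 1.54, Gucy1a1 at 1.14, Tacc1 at 1.11, H19 at −6.32, Adrb3 at −2.7, Prom2 at −2.41 and Fmn1 at −1.95.

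Each count was set against other splits of the same libraries. Only the real split, 1 of 100, gave as many genes for non-tumour liver in IKO (1172, highest other 7), SKO (2965, 125), BKO (2540, 323) and MKO (351, 112). The same held for the interactions of IKO (9, 6), SKO (736, 51), BKO (86, 3) and MKO (44, 9), where the mean knockout effect was removed first. The share of splits lay under 0.05 there, as it did with 1 of 35 for tumours of IKO (467, 330) and SKO (223, 121). It was also 1 of 35 for tumour against non-tumour liver in WT of sequencing group 1 (5460, 1933), IKO (4319, 1360) and SKO (5148, 1440). For age in sequencing group 1 (908, 114) the same share was found. Shares of 1 of 100 and 1 of 35 are the lowest these splits can give. They were not adjusted for the number of comparisons, so they make chance less likely without excluding it. Leaving out 1 library reached below the highest other split for the interaction of IKO (1 to 103) and tumours of IKO (191 to 580) and SKO (108 to 357). Neither these counts nor their genes are settled. For the difference of tumour effect 3 of 100 splits gave as many in IKO (16, 106), a share under 0.05 that does not exclude chance. The replicate block gave 0 genes there and leaving out 1 library 3 to 84, so the 16 genes are not settled either. In SKO 15 of 100 splits (4, 58), in BKO 9 (4, 123) and in MKO 14 (17, 582) gave as many, shares above 0.05. Highest others several times the real count, in all 4 differences and in BKO tumours, point to a structure of these libraries, whose cause was not tested. In sequencing group 2 the 10 splits are too few for a share under 0.05, with 3 giving as many in BKO tumours (71, 219) and 2 in MKO tumours (523, 574). There 1 of 10 did in tumour against non-tumour liver of WT (3510, 247), BKO (1907, 586) and MKO (2245, 1759) and in age (223, 2). For BKO, whose same-number libraries correlated, the 3 other splits parting as many pairs reached 46.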

How the results depend on the processing

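The alternatives added after the data were seen were limma-voom, the doubted library, lists with 1 library left out, concordance from different stages and a block for MKO at 8 months, and the cause of each change was not tested. Depth limits low genes, whose changes the transform understates. The deposited log2 values take no pseudocount, and on the recovered reads limma-voom was run but not edgeR or DESeq2. Library weights gave 810 genes for MKO non-tumour liver and 196, 1950, 917 and 400 for the interactions of IKO, SKO, BKO and MKO. They gave 112, 27 and 207 for tumours of SKO, BKO and MKO, 87, 80 and 3 for the differences of tumour effect of IKO, SKO and MKO, and 1714 and 840 for age in sequencing groups 1 and 2. Only the groups of the comparison gave 572 for MKO non-tumour liver, and 149 for the MKO interaction. They gave 35, 33, 1 and 0 for tumours of IKO, SKO, BKO and MKO, and 9, 1, 0 and 0 for their differences. They gave 1741, 12 and 82 for tumour against non-tumour liver of WT in sequencing group 2, BKO and MKO, and 511 and 82 for age. The replicate block gave 0, 1, 0 and 0 for the differences of IKO, SKO, BKO and MKO and 924 and 1151 for tumour against non-tumour liver of BKO and MKO. Quantile normalization gave 477 for the SKO interaction, 31 for the SKO difference and 2 lists, and the preset correlation of 0.01 gave 233 lists. The stricter filter gave 2 and 9 for the differences of SKO and MKO, and limma-voom 0 and 9 there and 52 for the BKO interaction. Concordance turned negative with effects from different stages for IKO and BKO (−0.012) and IKO and MKO (−0.006), and was 0.073 for IKO and SKO, 0.181 for SKO and MKO and 0.094 for BKO and MKO. Leaving out 1 stage gave 0.283 (1 month) to 0.352 (8 months) for IKO and SKO, 0.041 (5 months) to 0.182 (1 month) for IKO and BKO and 0.266 (8 months) to 0.458 (5 months) for SKO and MKO. The SE of r from leaving out each stage in turn was largest for BKO and MKO (0.231) and SKO and BKO (0.148).

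Leaving out 1 library in turn gave 781 to 1397 (IKO), 2674 to 3167 (SKO), 2163 to 2504 (BKO) and 180 to 431 (MKO) genes in non-tumour liver. For interactions it gave 1 to 103, 481 to 1177, 11 to 174 and 17 to 96, for tumours 191 to 580, 108 to 357, 15 to 93 and 117 to 786, and for differences 3 to 84, 2 to 48, 2 to 26 and 8 to 137, in the same order. For tumour against non-tumour liver it gave 4875 to 5276 (WT of sequencing group 1), 3442 to 4251 (IKO), 4365 to 4965 (SKO), 2607 to 3877 (WT of sequencing group 2), 780 to 2517 (BKO) and 1034 to 2809 (MKO), for age 485 to 965 and 37 to 146, and for lists 0 to 3, more than 0 for 10 libraries. Of results of named genes 0 reversed in the alternatives run, with 1551 in each but 1472 under the stricter filter and 101 without the doubted library. Without a filter nothing could differ, because the filter removed no gene. Calls were lost in 330 with only the groups of the comparison, 88 with the replicate block, 62 with library weights, 59 with limma-voom and 30 with quantile normalization, and in 1131 of 20108 results with 1 library left out. Without the library labelled SKO 3m replicate 2 the counts were 3167 for non-tumour liver and 797 for the interaction.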

Other observations

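The observations here were chosen after the values were seen, and no further tests were run on them. Of pericentral genes, Cyp2e1, Slc1a2 and Oat spread more widely between BKO libraries at 5 months than at 3 months. Cyp2e1 held 78.6, 67.5 and 92.9 normalised reads in the 3 BKO libraries at 1 month and 41.8, 157.7 and 43.2 at 3 months, then 1055.6, 200.1 and 2361.6 at 5 months and 597.7, 3938.0 and 1711.0 in non-tumour liver at 8 months. Slc1a2 held 13.6, 8.3 and 12 at 3 months and 168.9, 11 and 222.6 at 5 months. Oat, ornithine aminotransferase, held 12.7, 9.3 and 7.2 at 3 months and 107.7, 12.6 and 216.7 at 5 months. The library labelled replicate 2 was thus lowest for all 3 genes at 5 months. Glul, glutamine synthetase of the innermost pericentral hepatocytes, averaged 657.8 in BKO and 7075 in WT at 3 months, and 438.2 and 1935 in tumours.

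The number of genes that differed between knockout and WT at single stages was unequal. In IKO 1189 genes passed at 1 month, 26 at 3 months, 188 at 5 months and 26 at 8 months, and in SKO 2085, 673, 780 and 652. The 673 at 3 months include the library labelled SKO 3m replicate 2, which lacked the SKO difference. In BKO the counts were 567, 200, 835 and 637. Pebp1 in tumours averaged 786.5 in SKO and 269.8 in WT.

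Ctnnb1 rose in tumours of all genotypes, by 1.34 in WT of sequencing group 1, 1.499 in SKO, 0.92 in IKO, 0.66 in WT of sequencing group 2, 0.54 in BKO and 0.42 in MKO. Its WT level differed between sequencing groups, 581.1 and 182.0 normalised reads in tumours, so levels were compared only within a sequencing group. Genes of the Y chromosome were measured in every library, with Ddx3y at 24 reads or more, and the labels do not give the sex of the animals.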
